A study of Arabidopsis thaliana with 24 samples.

How the data were processed

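The series compared rosette leaves of Arabidopsis thaliana plants treated or not treated with silicon and either healthy or diseased with Erysiphe cichoracearum, a powdery mildew fungus that grows on the leaf surface and feeds from epidermal cells. There were 12 plants, 3 in each of 4 groups, called here control, pathogen, silicon, and silicon with pathogen. Silicon dose, plant age and time from inoculation to harvest were not given in the sources used here. Total RNA of each plant was hybridised on 4 of 24 Agilent Arabidopsis 3 arrays, each carrying 2 plants labelled with Cy3 and Cy5. Plants of the same number formed a closed loop of 4 pairs (control with pathogen, control with silicon, pathogen with silicon and pathogen, silicon with silicon and pathogen), and each pair was hybridised in both dye orientations. The direction of every ratio was taken from the dyes given in the labels.

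Per the file headers, the scanner files gave for each of 39941 spots the mean intensity and the median local background intensity of both channels, neither of them corrected, beside processed intensities that the Agilent software had background-subtracted and dye-normalised. Per the file headers they also gave log10 ratios of the processed intensities, Cy5 over Cy3, made by the software and set to 0 or a limit for some dim spots. They served here only for comparison with the deposited value table. The software was Feature Extraction A.7.5.1 or 8.5.1.1, per the file headers, and each version had read a single dye orientation of every pair. Version and dye orientation could therefore not be told apart. The headers gave 5 extraction or scan days, and every array was on its own slide. The deposited value table held log2 ratios of Cy5 over Cy3 made by the authors with limma, per the submitters' processing notes, which gave no version and no steps. Its values followed the scanner ratios in spot order with a correlation between 0.964 and 0.994 and a slope between 0.848 and 1.05, whereas matching by feature number gave correlations between -0.025 and 0.013, so spot order was used. Scale and direction were taken from this comparison, and its centring stayed unknown. The medians of its arrays, for replicates 1, 2 and 3 in turn, were 0.0208, 0.0875 and 0.0879 with control in Cy3 and pathogen in Cy5, and 0.134, 0.134 and 0.139 with the dyes swapped. They were 0.087, 0.115 and 0.13 with control in Cy3 and silicon in Cy5, and 0.156, 0.205 and 0.127 swapped. With pathogen in Cy3 and silicon with pathogen in Cy5 they were 0.15, 0.192 and 0.151, and 0.0711, 0.112 and 0.0773 swapped. With silicon in Cy3 and silicon with pathogen in Cy5 they were 0.137, 0.191 and 0.0953, and 0.101, 0.118 and 0.0725 swapped.

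Background was corrected with limma's normexp method (offset 50) on the mean and background intensities, and log2 ratios were normalised by loess within each array, with the 2256 control spots at weight 0. Control spots were then left out, and spots that the software had marked as non-uniform or as population outliers were set to missing, between 0.199% and 7.56% of the spots of an array (median 1.06%). These marks fell mainly on bright spots: among the brightest 2% of probes a mean of 17.9% was left out per array, against 0.109% among the dimmer 50%. A dye-swap pair then rested on a single orientation for 4.62% of the pairs over all genes, but for 36.2% in the photosystem list and 38.4% in the carbon fixation list, so keeping those spots was added as an alternative. Saturated spots were kept. Replicate spots were averaged for 23 probes, the arrays of a dye swap were turned the same way and averaged, and the 4 ratios of each loop were solved by least squares for its 4 plants. A dye bias of a gene cancels in this average only where it is equal in both software versions, and it drops out of the interaction within either version. Within a single version it stays in full in every comparison of 2 groups, with opposite sign in the other version. The misfit of the loops had an SD over genes between 0.25 and 0.33 log2.

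A probe was kept where it was well above background in at least 9 of the 12 channel readings of at least 1 group. That left 24958 of 37478 probes, which stood for 20355 loci; 4 of these had no value in any loop, and 20351 were tested. A locus was represented by its brightest probe, and 375 loci had more than 1. Called probes of such a locus differed in sign at 12 loci for the pathogen effect without silicon, at 13 with silicon, at 0 for the silicon effect in healthy plants and at 2 in diseased plants. Locus codes came from the array's own annotation and matched the reference annotation (assembly TAIR10.1, used here for names only) for 20228 loci, or 99.4%, of which 8715 had a symbol. Probe positions are those of the array's annotation, whose genome build was not given in the sources used here. There were 8812 probes that named a chromosome region and 2430 that named another sequence in place of a locus; they entered no gene count.

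Plant values were fitted with limma (version 3.58.1 in R 4.3.3, with data.table, version 1.17.8), with group as the factor and the loop as a block, because ratios exist only within a loop. The fit had 6 residual degrees of freedom and 2.4 prior degrees of freedom from the moderated variance. There were 5 contrasts: the effect of the pathogen without silicon, the effect of the pathogen with silicon, the effect of silicon in healthy plants, the effect of silicon in diseased plants, and the interaction, which is the pathogen effect with silicon minus that without. All tests were 2-sided, and Benjamini-Hochberg adjusted p-values below 0.05 over the 20351 genes were taken as calls. Values are log2 fold changes with the SD over the 3 loops (n = 3 plants per group); a few genes with a missing reading have a standard error in place of the SD.

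The groups, the contrasts, the fit, 25 gene lists holding 341 genes (323 measured), most of the alternatives and the rule for named genes were fixed before the data were examined. The lists covered salicylate, jasmonate, ethylene, camalexin and indole metabolism, powdery mildew resistance, immune receptor signalling, oxidative stress and detoxification, protein folding in the endoplasmic reticulum, photosystems and antenna, carbon fixation, nitrogen assimilation, sugar transport, senescence, abscisate with cold and drought, phenylpropanoid and lignin, flavonoid, heat shock, circadian clock, phosphate starvation, NIP aquaporins, markers of root, flower, vascular tissue, and guard cells with trichomes, and reference genes. Named per contrast were the 12 largest rises and the 12 largest falls among called genes with a symbol and a single sign in the 3 loops, up to 4 called members of each list, and 9 genes in every contrast (PR1, PR2, PR5, ICS1, PAD3, PDF1.2a, VSP2, LHCB1.3 and RBCS1A). Genes whose function was not surely known were left out of the text. Lists with at least 3 measured genes were tested with limma's camera against all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast, and again with the correlation estimated from the data. Camera compares mean test statistics, so its direction can differ from that of a median near 0. Each list was also counted with its genes adjusted over the list alone. The size of the response with silicon relative to that without was computed per loop on genes chosen in the other loops by the mean of both pathogen effects; 3 loops allow no 2-sided exact p below 0.25, so it has no test.

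Median Cy3 intensities per array were 65.1 to 195 (median 97.9) over a background of 32 to 58, with 0 to 30 saturated spots. Arrays with silicon with pathogen in Cy3 had 118 to 195, others at most 126, and over 8 saturated spots occurred only among the former. Median Cy5 intensities were 50.5 to 85.3 (median 61) over 38 to 48, with 0 to 2 saturated spots. Of probe spots 59% to 89.4% were well above background in Cy3 and 36.2% to 70.4% in Cy5. Signals and plant number limit every value's precision. No pair of arrays shared more than 0.00265% of spots with equal intensities in both channels, so all 24 were used. Same-numbered plants deviated together from their group on different arrays of the same software version, with a median correlation over genes of 0.476 (0.06 to 0.703), against -0.159 for plants of different numbers. Across software versions the median was 0.03 (-0.34 to 0.386).

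The fit was tested on simulated data of 15335 genes with 50 genes changed per fold size. For the pathogen effect without silicon, 48%, 94%, 86% and 98% of changes of 1.25, 1.5, 2 and 4 fold were recovered with 8 false calls. For silicon in healthy plants the shares were 54%, 78%, 98% and 100% with 13 false calls. In diseased plants they were 40%, 92%, 88% and 98% with 10. For the interaction, with the pathogen group changed, they were 16%, 68%, 78% and 94% with 9. These rates need not hold where dye bias differs between versions.

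Alternatives fixed in advance were no background subtraction, median centring in place of loess, scaling between arrays, the Agilent processed intensities, the authors' value table, no filter or a filter on every channel reading, the mean of all probes of a gene, 24 arrays or 12 dye-averaged ratios as independent, separate channels with no replicate block, direct arrays of each pair, a minimum fold of 2, leaving out each replicate, the extraction or scan batch as a block, and an estimated correlation for the lists. Chosen after the data were seen were the fits within each software version, the form of the day block (a fit of the 24 arrays with the arrays of a dye swap as correlated, without and with day terms), the fit with outlier spots kept, and 15 gene families. Of loess and median centring, only loess adjusts for a dye difference that depends on intensity. With median centring the median over all genes moved from near 0 to 0.11 for the pathogen effect without silicon, 0.36 with silicon, 0.25 for the silicon effect in diseased plants and 0.26 for the interaction, and it stayed at -0.01 in healthy plants; with the authors' table it was 0.13 for the interaction. Changes are therefore given relative to the median of all genes under loess. Day was nearly confounded with the interaction, whose unscaled standard error rose from 0.395 to 0.856 with day terms, against 0.342 to 0.484 for the silicon effect in diseased plants.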

Results

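Values are log2 changes ± the SD over the 3 loops, with n = 3 plants in each group. Each comparison was also computed within the first and the second software version and with day as a block, and batch medians are given in that order, with the adjusted p where a list gained or lost its call. Counts in a list with its genes adjusted over the list alone were the same unless given. Medians of uncalled lists within 0.1 of 0 are given as values only, since the sign of several of them turned with the scaling.

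Powdery mildew in plants without silicon raised genes of the salicylate response together. PR1 (AT2G14610, chromosome 2, 6249455 to 6249396), a secreted protein used as a marker of salicylate signalling, rose by 5.10 ± 0.36, or 34.3-fold (adjusted p = 3.24e-07), with 0 saturated readings in either group. Its relative PRB1 rose by 4.96 ± 0.49, the osmotin-like OSM34 (AT4G11650, chromosome 4, 7025327 to 7025268) by 4.76 ± 0.88, and the thaumatin-like PR5 by 3.28 ± 0.51. PR2, a beta-1,3-glucanase, rose by 2.52 ± 0.53, and ICS1, which makes the precursor of salicylate, by 1.82 ± 0.27 (1.08 on its other probe). All 22 measured genes of the salicylate list rose, with a median of 1.54 (adjusted p = 2.68e-11, and adjusted p = 0.162 with an estimated correlation). PBS3, which acts in salicylate synthesis after ICS1, rose by 2.80 with a standard error of 0.13. The list's batch medians were 1.74, 1.44 and 1.57.

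Camalexin, the main indole phytoalexin of Arabidopsis, is made from tryptophan, and 13 of 14 genes of the camalexin and indole list rose while 0 fell (median 1.60, adjusted p = 2.59e-06, and adjusted p = 0.182 with an estimated correlation). Adjusted over the list alone, 13 rose and 1 fell. CYP79B2 (AT4G39950, chromosome 4, 18527184 to 18527243), which turns tryptophan into indole acetaldoxime, rose by 4.22 ± 0.71 (adjusted p = 3.96e-06). CYP71A13, the next enzyme, rose by 3.47 ± 0.40 from a level that was well above background in 6 of 12 readings of control plants. PAD3 (AT3G26830, chromosome 3, 9890709 to 9890768), which makes camalexin itself, rose by 2.31 ± 0.47, and the tryptophan synthase subunit AT3G54640 by 2.68 ± 0.14. The nitrilase NIT2 rose by 3.69 ± 1.04. Batch medians of the camalexin and indole list were 1.79, 1.59 and 1.64.

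Of 21 immune receptor signalling genes 17 rose and 1 fell (median 0.70, adjusted p = 2.81e-06, and adjusted p = 0.182 with an estimated correlation), among them the transcription factors WRKY53 (1.70 ± 0.13) and WRKY33 (1.63 ± 0.27), the wall-associated kinase WAK1 (1.60 ± 0.32) and the MAP kinase MPK11 (1.59 ± 0.098). Of 16 powdery mildew resistance genes 10 rose and 2 fell (median 0.71, adjusted p = 0.0203, and adjusted p = 0.182 with an estimated correlation). MLO6, a relative of the barley susceptibility gene MLO, rose by 1.91 ± 0.20, and the membrane fusion proteins SNAP33 and SYP122 rose by 1.88 ± 0.28 and 1.88 ± 0.24. PMR6, a pectate lyase-like gene needed for full susceptibility to powdery mildew, fell by 1.96 (SD 0.12). The batch medians were 0.82, 0.57 and 1.01 for immune receptor signalling and 0.48, 0.55 and 0.66 for powdery mildew resistance, which did not pass in the first version (adjusted p = 0.272).

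Detoxification and protein folding genes rose as groups. Of 18 oxidative stress and detoxification genes 13 rose and 3 fell (median 0.97, adjusted p = 0.000668, and adjusted p = 0.182 with an estimated correlation). The glutathione transferases GSTF6 and GSTF7 (AT1G02920, chromosome 1, 659303 to 659244) rose by 4.15 ± 0.33 and 4.03 ± 0.22, and the peroxidase PRXCB by 3.28 ± 0.44. Of 11 genes for protein folding in the endoplasmic reticulum 10 rose and 0 fell (median 1.1, adjusted p = 3.94e-05, and adjusted p = 0.182 with an estimated correlation), with the chaperone BIP2 at 1.92 ± 0.069 and the disulfide isomerase PDIL1-2 at 1.57 ± 0.14. The trypsin inhibitor KTI1 rose by 4.25 ± 0.78. Their batch medians were 0.52, 0.87 and 0.84 for oxidative stress and 1.19, 1.2 and 1.16 for protein folding.

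Photosynthesis genes fell together. Of 30 photosystem and antenna genes 29 fell and 0 rose (median -2.21, adjusted p = 1.78e-10, and adjusted p = 0.182 with an estimated correlation), with the antenna genes LHB1B1 at -3.21 ± 0.69 and LHCB5 at -2.66 ± 1.31 and the oxygen-evolving complex gene PSBP1 at -2.59 ± 0.36. Of 18 carbon fixation genes 15 fell and 0 rose (median -1.79, adjusted p = 1.46e-06, and adjusted p = 0.182 with an estimated correlation), including the Rubisco small subunit RBCS2B (-2.89 ± 0.91) and the plastid fructose-1,6-bisphosphatase HCEF1 (-2.33 ± 0.27). The aldolase FBA5 fell by 3.36 (SD 0.41). LHCB1.3 stood at -1.83 (standard error 0.83, adjusted p = 0.12) and RBCS1A, with 7 of 12 control readings saturated, at -1.23 ± 1.78 (adjusted p = 0.132). Neither passed the test. Batch medians were -1.40, -2.68 and -1.97 for photosystems and -1.38, -2.49 and -1.92 for carbon fixation.

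Genes of leaf ageing and of the phenylpropanoid pathway rose. Of 10 senescence genes 8 rose and 1 fell (median 1.40, adjusted p = 0.00073, and adjusted p = 0.227 with an estimated correlation). SAG13 (AT2G29350, chromosome 2, 12608984 to 12609141), a short-chain dehydrogenase gene induced in ageing leaves, rose by 4.46 ± 0.10 (adjusted p = 6.94e-08; 4.81 on its other probe), the transcription factor NAP by 2.46 ± 0.52, and SAG21 by 2.32 ± 0.20. DIN2, a beta-glucosidase gene induced in the dark, rose by 3.69 ± 1.3. Of 14 phenylpropanoid and lignin genes 11 rose and 1 fell (median 1.19, adjusted p = 0.000117, and adjusted p = 0.335 with an estimated correlation), with the methyltransferase COMT1 at 3.14 ± 0.050, C4H at 2.53 ± 0.34 and PAL1 at 2.25 ± 0.41. Of 7 flavonoid genes 5 fell and 0 rose (median -0.24, adjusted p = 0.0129, and adjusted p = 0.182 with an estimated correlation). Chalcone synthase CHS (chromosome 5, 4489704 to 4489763) fell by 1.96 (SD 0.078) and F3H by 0.51 (SD 0.099). Batch medians were 1.68, 1.31 and 1.76 for senescence, 1.35, 0.996 and 1.2 for phenylpropanoids, and -0.25, -0.33 and -0.30 for flavonoids, which did not pass in the second version (adjusted p = 0.0607).

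The other hormone lists did not pass in the main fit. Of 20 jasmonate genes 9 rose and 5 fell (median 0.11, adjusted p = 0.292; 6 fell adjusted over the list alone). The tyrosine aminotransferase TAT3 (2.81 ± 0.29) and the repressor JAZ1 (1.89 ± 0.086) rose, while the allene oxide cyclase AOC2 fell by 1.29 (SD 0.38) and VSP2 by 0.71 (SD 0.21). The defensin PDF1.2a stood at 0.68 ± 1.38 (adjusted p = 0.288). Of 22 ethylene genes 7 rose and 0 fell (median 0.15, adjusted p = 0.0508), among them PR4 (2.38 ± 0.13) and ACS6 (1.56 ± 0.32). The ethylene list passed in the second version, the day block, with median centring and with outlier spots kept (adjusted p = 0.0414, 0.0243, 0.0223 and 0.0478). Of 21 abscisate, cold and drought genes 5 rose and 12 fell (median -0.52, adjusted p = 0.129; 7 rose adjusted over the list alone). RD22 was at -2.35 ± 0.31 and KIN2 at -2.05 ± 0.28. The abscisate list passed in the first version and with median centring (adjusted p = 0.02 and 0.0186).

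Of 6 sugar transport and invertase genes 4 rose and 2 fell (median 0.63, adjusted p = 0.239). The cell wall invertase CWINV1 rose by 2.83 ± 0.65 and the hexose carrier STP13 by 2.22 ± 0.10, while STP1 fell by 1.89 (SD 0.38) and the phloem sucrose carrier SUC2 by 0.75 (SD 0.31). Of 10 nitrogen assimilation genes 3 rose and 4 fell (median -0.0023 with loess and 0.44 with median centring, adjusted p = 0.748). GDH2 was at 1.58 ± 0.30 and the plastid glutamine synthetase GLN2 at -1.73 (standard error 0.33). Of 10 phosphate starvation genes 5 rose and 2 fell (median 0.34, adjusted p = 0.152), with the phosphatase PAP17 at 2.34 ± 0.26 and the carrier PHT1;4 at 1.15 ± 0.41. Among the 5 NIP aquaporins, the family that holds the silicon channels of grasses, 1 fell and 0 rose (median -0.098, adjusted p = 0.239). NIP6;1 fell by 0.49 (SD 0.18).

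Of 7 heat shock genes 2 rose (median 0.21, adjusted p = 0.628, and 0.0249 in the second version), HSP90.1 by 0.64 ± 0.12 and HSP17.6II by 0.24 ± 0.12. Of 12 circadian clock genes 5 fell (median -0.17 with loess and 0.090 with median centring, adjusted p = 0.227), among them LUX by 0.65 (SD 0.13) and LHY by 0.51 (SD 0.29). Of 7 vascular markers 6 fell (median -0.19, adjusted p = 0.026, and adjusted p = 0.182 with an estimated correlation). XCP2 was at -0.72 ± 0.089 and IRX5 at -0.57 ± 0.085; the batch medians were -0.16, -0.29 and -0.23, and the list did not pass in the first version or the day block (adjusted p = 0.0786 and 0.11). Of 4 root markers 2 rose (median 0.064, adjusted p = 0.485). RCI3 was at 0.33 ± 0.072. Of 6 flower markers 2 fell (median -0.032, adjusted p = 0.485). SEP3 was at -0.52 ± 0.072 but 0.63 in the second software version. Of 4 guard cell and trichome markers 1 rose and 2 fell (median -0.13, adjusted p = 0.485). The channel gene KAT1 rose by 0.28 ± 0.098 and the myrosinase TGG1 fell by 1.76 (SD 0.21). Of 8 reference genes 1 rose (median 0.15, adjusted p = 0.707; 0 adjusted over the list alone), EF1A by 0.48 (standard error 0.086, adjusted p = 0.0402). Its value was -0.57 with median centring, -0.13 with 24 arrays as independent and -0.12 with correlated dye-swap arrays.

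Among the largest falls with a known name were EXL3 (AT5G51550, chromosome 5, 20956969 to 20956910), a gene of the EXORDIUM-like family, at -4.24 (SD 0.075, adjusted p = 3.47e-07), and the beta-galactosidase BGAL1 (AT3G13750, chromosome 3, 4515676 to 4515735) at -3.84 (SD 1.3). The water channels DELTA-TIP and PIP3 fell by 3.65 (SD 0.11) and 3.06 (SD 0.46), the gibberellin-regulated GASA6 by 3.06 (SD 0.44), and the wall enzyme gene XTH4 by 2.96 (SD 0.13). In all, 10785 of 20351 genes (53%) passed the test, 5428 higher and 5357 lower, and 1905 of them changed at least 2-fold (938 higher, 967 lower). Higher genes made up 50.3% of the calls with loess and 71.4% of 7214 calls with median centring. The separate software versions called 8607 and 11339 genes and the day block 10895; across genes, which are not independent replicates, the changes in the 2 versions correlated at 0.75.

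**Figure D1:**
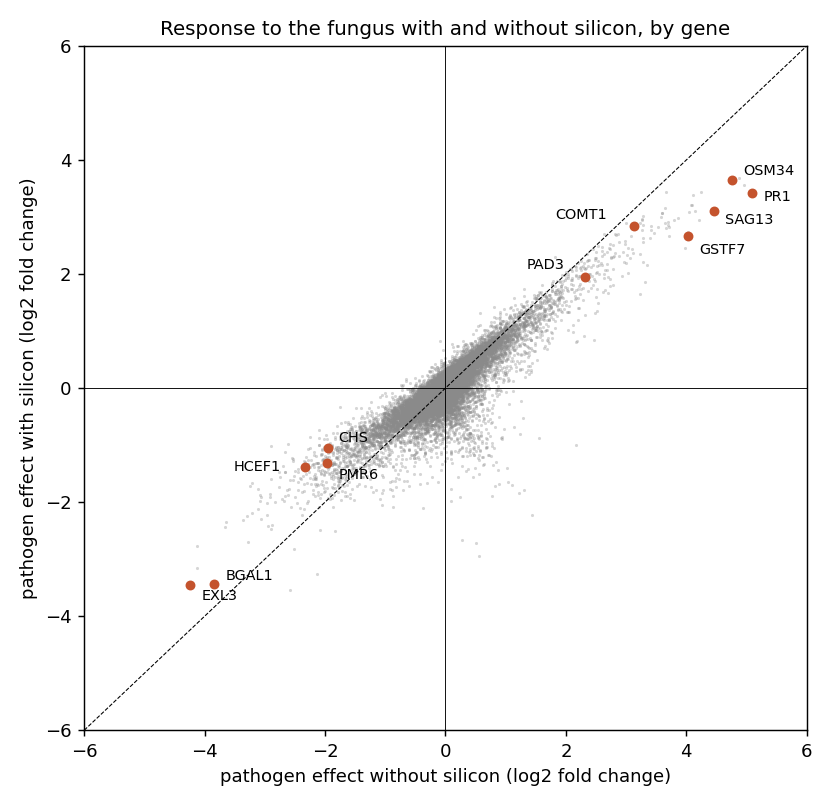
Each point is 1 gene: the log2 change with the fungus in plants without silicon (horizontal) and with silicon (vertical), with the line of equality dashed. Labelled defence genes such as PR1 (5.10 and 3.41) lie below that line, and falling genes such as HCEF1 (-2.33 and -1.39) lie above it.

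In plants with silicon the fungus raised many of the same defence genes. OSM34 rose by 3.65 ± 0.58, PRB1 by 3.56 ± 0.77 and KTI1 by 3.44 ± 0.50; PR1 rose by 3.41 ± 0.39, or 10.7-fold (adjusted p = 2.73e-06). Of the 12 PR1 readings in diseased silicon plants 4 were saturated, which can make that value too small. PR5 rose by 2.85 ± 0.083, PR2 by 2.04 ± 0.27, ICS1 by 1.69 ± 0.13 (1.14 on its other probe), and FMO1, a gene of systemic resistance, by 2.44 ± 0.16 from 6 of 12 readings well above background in healthy silicon plants. Of the 22 salicylate genes 20 rose and 0 fell (median 1.65, adjusted p = 5.22e-10, and adjusted p = 0.214 with an estimated correlation), 21 adjusted over the list alone. The batch medians were 1.74, 1.33 and 1.74.

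Camalexin and indole genes rose again, 12 of 14 with 0 lower (median 1.19, adjusted p = 3.85e-05, and adjusted p = 0.304 with an estimated correlation). CYP79B2 rose by 2.95 ± 0.46, CYP71A13 by 2.72 ± 0.27 and PAD3 by 1.96 ± 0.34. Of the 21 immune receptor signalling genes 17 rose and 1 fell (median 0.63, adjusted p = 1.67e-05, and adjusted p = 0.369 with an estimated correlation), including WRKY53 at 1.57 ± 0.13 and WAK1 at 1.51 ± 0.38. Of the 16 powdery mildew resistance genes 8 rose and 2 fell (median 0.21, adjusted p = 0.11, and 0.00989 in the second version). MLO6 was at 1.88 ± 0.083, SNAP33 at 1.54 ± 0.16 and PMR6 at -1.31 ± 0.30. Batch medians were 0.98, 1.02 and 1.12 for camalexin and 0.89, 0.66 and 0.49 for immune receptor signalling; camalexin did not pass in the first version (adjusted p = 0.0815).

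Of the 18 oxidative stress and detoxification genes 11 rose and 1 fell (median 0.72, adjusted p = 0.00792, and adjusted p = 0.369 with an estimated correlation), or 12 and 3 adjusted over the list alone; GSTF7 rose by 2.66 ± 0.32 and PRXCB by 2.22 ± 0.15, and outside the list GSTU10 rose by 3.17 ± 0.34 and the trypsin inhibitor TI1 by 3.08 ± 0.18. Of 11 endoplasmic reticulum folding genes 10 rose and 0 fell (median 0.97, adjusted p = 0.000911, and adjusted p = 0.369 with an estimated correlation). BIP2 was at 1.79 ± 0.085 and PDIL1-2 at 1.67 ± 0.16. Of 10 senescence genes 8 rose and 1 fell (median 1.05, adjusted p = 0.00792, and adjusted p = 0.369 with an estimated correlation). SAG13 rose by 3.10 ± 0.20 (4.37 on its other probe) and NAP by 1.80 ± 0.56. Of 14 phenylpropanoid and lignin genes 12 rose and 1 fell (median 0.88, adjusted p = 0.000144, and adjusted p = 0.369 with an estimated correlation; 13 rose adjusted over the list alone). COMT1 was at 2.84 ± 0.25 and C4H at 2.48 ± 0.11. Of the 7 flavonoid genes 1 fell (median -0.048 with loess and 0.055 with median centring, adjusted p = 0.411), CHS by 1.04 (SD 0.22). The batch medians were 0.41, 0.57 and 0.57 for oxidative stress, 1.12, 0.83 and 0.94 for protein folding, 1.05, 1.11 and 0.95 for senescence, and 0.99, 0.82 and 0.74 for phenylpropanoids. In the first version oxidative stress, protein folding and senescence did not pass (adjusted p = 0.0815, 0.283 and 0.136), nor did senescence in the second (adjusted p = 0.0656), nor oxidative stress and senescence with median centring (adjusted p = 0.051 for both).

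Photosynthesis genes fell in silicon plants as well. Of 30 photosystem and antenna genes 28 fell and 0 rose (median -1.36, adjusted p = 1.88e-08, and adjusted p = 0.369 with an estimated correlation; 30 fell adjusted over the list alone), among them LHCB2.2 at -3.55 ± 1.58, LHCB1.3 at -2.5 (standard error 0.83, adjusted p = 0.0479) and PSAL at -2.23 ± 0.83. Of 18 carbon fixation genes 13 fell and 0 rose (median -1.02, adjusted p = 0.00016, and adjusted p = 0.369 with an estimated correlation), including HCEF1 by 1.39 (SD 0.18) and FBA1 by 1.38 (SD 0.028). RBCS1A, with 9 of 12 readings saturated in diseased silicon plants and 3 in healthy ones, stood at -1.2 ± 0.86 (adjusted p = 0.135). The ferric reductase FRO7 fell by 3.26 (SD 0.87), with -2.27 on its other probe. EXL3 fell by 3.46 (SD 0.30), and BGAL1 fell by 3.43 (SD 1.01). Batch medians were -0.76, -1.95 and -1.89 for photosystems and -0.28, -1.60 and -1.26 for carbon fixation, which did not pass in the first version (adjusted p = 0.238).

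Of 21 abscisate, cold and drought genes 4 rose and 12 fell, with a median of -0.62 that turned to 0.030 with median centring (adjusted p = 0.0198, and adjusted p = 0.62 with an estimated correlation). RD22 fell by 2.13 (SD 0.16) and COR47 by 1.53 (SD 0.62). Of 20 jasmonate genes 8 rose and 5 fell (median 0.12, adjusted p = 0.411; 10 and 5 adjusted over the list alone). TAT3 was at 2.70 ± 0.35, AOC2 at -1.35 ± 0.41 and VSP2 at -0.82 ± 0.42, while PDF1.2a stood at -0.73 ± 0.76 (adjusted p = 0.246). Of 22 ethylene genes 7 rose and 4 fell (median -0.0057 with loess and 0.59 with median centring, mean 0.16, adjusted p = 0.589; 6 and 4 adjusted over the list alone). PR4 was at 1.88 ± 0.26. Of 7 vascular markers 5 fell (median -0.28, adjusted p = 0.00792, and adjusted p = 0.35 with an estimated correlation). IRX5 was at -0.59 ± 0.013. Batch medians were -0.53, -0.60 and -0.64 for abscisate and -0.20, -0.36 and -0.28 for vascular markers. Abscisate did not pass in the second version (adjusted p = 0.193), and vascular markers did not in the first version, the day block and with median centring (adjusted p = 0.208, 0.16 and 0.0795).

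Of the 6 sugar genes 3 rose and 2 fell (median 0.65, adjusted p = 0.513). CWINV1 rose by 2.69 ± 0.30 and STP13 by 1.41 ± 0.38, while STP1 fell by 1.73 (SD 0.76) and SUC2 by 1.43 (SD 0.53). Of 10 nitrogen genes 2 rose and 3 fell (median -0.10 with loess and 0.71 with median centring, adjusted p = 0.971). GDH2 was at 1.43 ± 0.37 and GLU1 at -0.74 ± 0.17, the latter 0.22 with median centring. Of 10 phosphate starvation genes 5 rose and 1 fell (median 0.46, adjusted p = 0.0991, and 0.00175 in the day block). PAP17 was at 2.23 ± 0.26 and SPX1 at 1.39 ± 0.27. Of 5 NIP aquaporins 1 rose and 1 fell (median 0.012, adjusted p = 0.977; 1 and 0 adjusted over the list alone). NIP6;1 stood at -0.19 ± 0.083 but at 0.26 with median centring, 0.11 in the first software version and 0.090 with day as a block, and NIP1;2 at 0.15 ± 0.081 but at -0.064 in the second version.

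Of 7 heat shock genes 1 rose and 2 fell (median 0.032, adjusted p = 0.971; 0.27 and adjusted p = 0.00649 in the second version). HSP90.1 was at 0.66 ± 0.25 and HSP23.6 at -0.35 ± 0.12, the latter 0.40 with median centring and 0.53 in the second version. Of 12 clock genes 2 rose and 2 fell (median -0.066 with loess and 0.51 with median centring, adjusted p = 0.604; 1 and 1 adjusted over the list alone). ELF3 was 0.25 ± 0.075 and -0.042 in the second version, LUX -0.42 ± 0.20 and 0.092 with median centring, and GRP7 -0.96 ± 0.20 and 0.44 in the second version. Of 4 root markers 1 fell (median -0.025, adjusted p = 0.56, and 0.0334 with median centring), COBL9 at -0.91 ± 0.36 and 0.77 in the second version; of 6 flower markers 3 fell (median -0.12, adjusted p = 0.331, and 0.0334 with median centring). SEP3 was at -1.17 ± 0.30 and 0.35 in the second version. Of 4 guard cell and trichome markers 1 rose (median -0.0018 with loess and 0.33 with median centring, adjusted p = 0.971), KAT1 by 0.32 ± 0.13. Of 8 reference genes 3 rose (median 0.21, adjusted p = 0.637; 2 adjusted over the list alone). TIP41L rose by 0.31 ± 0.11, PP2AA3 by 0.29 ± 0.22, and EF1A by 0.45 (standard error 0.086), which was -0.19 in the second version.

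In all, 11251 of 20351 genes (55.3%) passed the test with silicon, 6032 higher and 5219 lower, and 1428 of them changed at least 2-fold (743 higher, 685 lower). Higher genes made up 53.6% of the calls with loess and 86.2% of 12354 calls with median centring. The software versions called 10663 and 9950 genes, with changes that correlated at 0.495 across genes, and the day block called 10373.

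**Figure D2:**
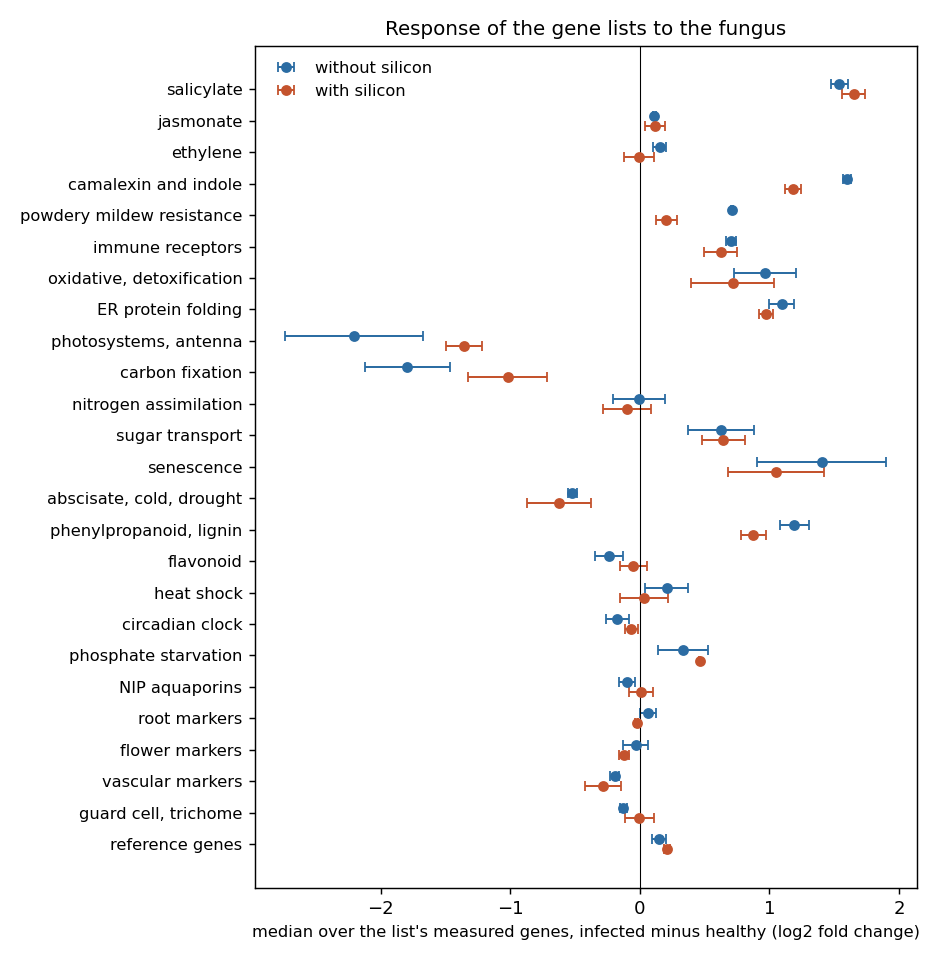
Median log2 change with the fungus of the 25 gene lists (horizontal axis) without silicon (blue) and with silicon (red), with bars for the SD over 3 loops. The photosystem median was -2.21 without and -1.36 with silicon, and the salicylate median 1.54 and 1.65; with median centring the abscisate median with silicon was 0.030 in place of -0.62.

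PR1, SAG13, CYP79B2, EXL3 and BGAL1 moved the same way with and without silicon, and so did most genes called without silicon. Of 5428 genes higher without silicon 4476 were also higher with silicon, against 1609 expected if the calls were independent, and of 5357 lower genes 3753 were also lower, against 1374; 25 and 16 were called in opposite directions. On the direct arrays of each pair, which share no plant, 3365 higher genes (1079 expected) and 2723 lower genes (834 expected) were shared, and the effects correlated at 0.853 over 19903 genes, which are not independent replicates. For genes that rose in the other loops by the mean of both pathogen effects, the changes averaged 0.59 without and 0.54 with silicon, a ratio of 0.922 ± 0.082 over 3 loops; for genes that fell they averaged -0.60 and -0.49, a ratio of 0.818 ± 0.118. Over all genes the median absolute change was 0.21 without and 0.22 with silicon. The ratios were not tested. With median centring the ratios were 1.75 and 0.565.

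**Figure D3:**
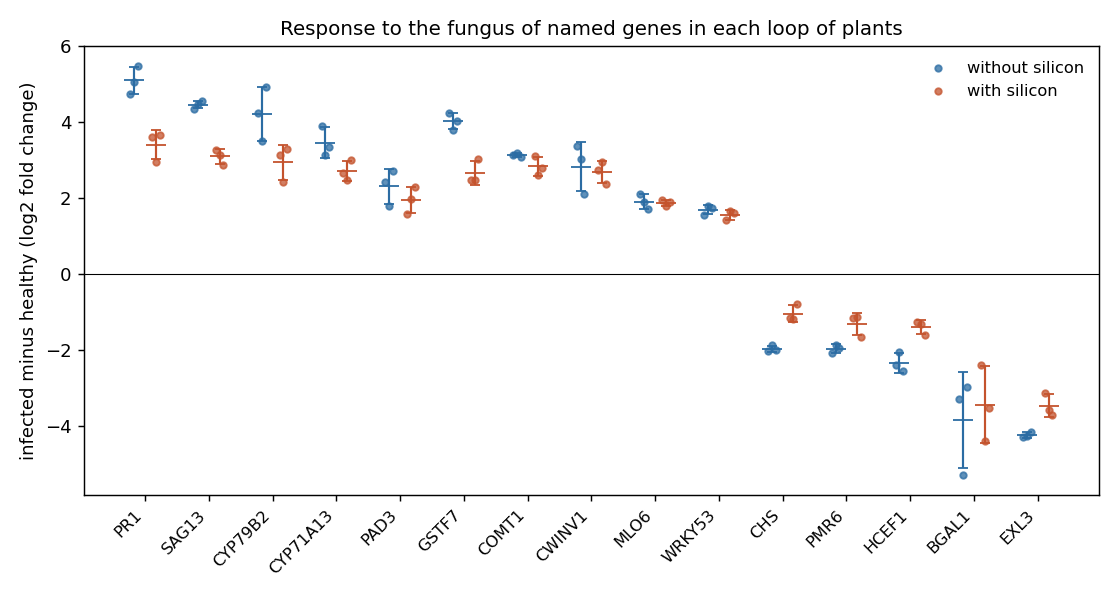
Log2 change with the fungus of single genes in each of 3 loops (small points) with mean and SD, without silicon in blue and with silicon in red. SAG13 was 4.46 without and 3.10 with silicon, PR1 5.10 and 3.41, and CHS -1.96 and -1.04.

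Silicon alone changed a single gene in healthy leaves. ARR15 (AT1G74890, chromosome 1, 28135312 to 28135253), a response regulator induced by cytokinin, fell by 0.47 (SD 0.062, adjusted p = 0.0414). Defence genes did not pass the test: PR1 stood at 0.81 ± 0.39 (adjusted p = 0.345), SAG13 at 0.68 ± 0.15 (0.59 on its other probe), PR2 at 0.77 ± 0.53, PR5 at 0.58 ± 0.51, GSTF7 at 0.52 ± 0.33, CYP79B3 at 0.35 ± 0.059 and CHS at -0.36 ± 0.12. ICS1 was 0.012 ± 0.086, PAD3 0.037 ± 0.33, PDF1.2a 0.82 ± 0.58, VSP2 -0.017 ± 0.34, LHCB1.3 -0.030 (standard error 0.83) and RBCS1A, with 7 control and 3 silicon readings saturated, -0.22 ± 0.80. By limma 1031 genes had an unadjusted p below 0.05, against 1018 expected by chance. ARR15 was not called without any 1 replicate, with no replicate block, no background subtraction, median centring or the Agilent processed intensities (0 calls in each). The deposited log2 values gave 2 calls, the first software version 0, the second 1564 and the day block 27, the last without ARR15. Across genes the silicon effects in the 2 versions correlated at -0.506, and 31.8% of genes had the same sign in both. On the arrays that paired control with silicon plants, the ratios of a dye swap correlated at 0.103, -0.408 and -0.406. The part of the silicon values that turned with dye and version thus varied more between genes than the part common to both.

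Several lists lay slightly off the other genes in healthy silicon leaves, with 0 members past the test over all genes. Medians were 0.048 for 22 salicylate genes (adjusted p = 0.0227; 1 rose adjusted over the list alone), 0.14 for 14 camalexin genes (adjusted p = 0.00405; 1 rose over the list alone), 0.088 for 18 oxidative stress genes (adjusted p = 0.0227) and 0.088 for 11 protein folding genes (adjusted p = 0.0248). Each had an adjusted p = 0.575 with an estimated correlation. They were 0.17 for 10 senescence genes (adjusted p = 0.0245; 1 rose over the list alone), -0.064 for 7 flavonoid genes (adjusted p = 0.0248; 2 fell over the list alone), -0.073 for 5 NIP aquaporins (adjusted p = 0.0248), and 0.070 for 14 phenylpropanoid genes (adjusted p = 0.0279, and 0.151 with median centring; -0.013 without replicate 3). The adjusted p with an estimated correlation was 0.705 for phenylpropanoids and 0.575 for the other 3. Without replicate 1 only 2 of the 8 lists passed, and without replicate 3 likewise 2. Batch medians were 0.045, 0.060 and 0.078 for salicylate, 0.25, 0.26 and 0.18 for camalexin, and 0.018, 0.12 and 0.18 for oxidative stress. They were likewise -0.12, 0.37 and 0.16 for protein folding, 0.33, -0.14 and 0.27 for senescence, 0.097, 0.040 and 0.18 for phenylpropanoids, -0.043, -0.047 and -0.18 for flavonoids, and -0.050, -0.095 and -0.16 for NIP aquaporins. In the day block salicylate, camalexin, oxidative stress, senescence and phenylpropanoids did not pass (adjusted p = 0.348, 0.119, 0.22, 0.25 and 0.22). In the first version none of the 8 passed, and in the second only camalexin and protein folding did (adjusted p = 0.00462 and 0.00351).

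None of the other lists passed in the main fit in healthy plants, but 3 passed in opposite directions in the software versions, where a gene's dye bias has opposite sign. Photosystem genes had a median of 0.012 (adjusted p = 0.904) and batch medians of 0.60, -0.36 and 0.41 (adjusted p = 4.52e-06, 0.00361 and 1.23e-06). Carbon fixation genes stood at 0.018 (adjusted p = 0.886), and at 0.36 and -0.26 in the versions (adjusted p = 0.0257 and 0.00462). Heat shock genes stood at -0.042 (adjusted p = 0.904), and at -0.22 and 0.21 (adjusted p = 0.00382 and 0.0475). Jasmonate, ethylene, powdery mildew resistance and immune receptor signalling genes had medians of 0.062, 0.028, 0.025 and 0.043 (adjusted p = 0.0985, 0.343, 0.724 and 0.105). Jasmonate and immune receptor signalling passed with outlier spots kept (adjusted p = 0.0332 and 0.0213), and ethylene and sugar genes with median centring (adjusted p = 0.0198 and 0.00334), as photosystems did (adjusted p = 0.0264). Nitrogen, sugar, abscisate, clock and phosphate genes had -0.0011, 0.18, 0.019, -0.054 and 0.035 (adjusted p = 0.488, 0.237, 0.471, 0.0653 and 0.29). Root, flower, vascular, and guard cell and trichome markers had 0.015, -0.040, -0.0074 and 0.017, and reference genes -0.042 (adjusted p = 0.484, 0.471, 0.723, 0.724 and 0.724).

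In diseased leaves, plants with silicon had more transcript of photosynthesis genes. RBCS2B (AT5G38420, chromosome 5, 15398442 to 15398383) was higher by 1.43 ± 0.62 (adjusted p = 0.0219), RBCS1B (chromosome 5, 15401578 to 15401519) by 1.2 ± 0.39, and SBPASE (AT3G55800, chromosome 3, 20722253 to 20722312), an enzyme of the Calvin cycle, by 1.09 ± 0.30. Of 18 carbon fixation genes 9 rose and 0 fell (median 0.79, adjusted p = 1.75e-05, and adjusted p = 0.414 with an estimated correlation; 12 rose adjusted over the list alone). Of 30 photosystem and antenna genes 14 rose and 0 fell (median 0.70, adjusted p = 1.6e-06, and adjusted p = 0.414 with an estimated correlation; 20 rose over the list alone). PSBQ1 was at 1.18 ± 0.39, LHCB6 at 1.13 ± 0.62, PSAN at 1.11 ± 0.49 and NPQ4 (AT1G44575, chromosome 1, 16875657 to 16875716), needed for the dissipation of excess light, at 1.1 ± 0.48. HPR, an enzyme of photorespiration, was higher by 1.15 ± 0.62 and the plastid ATP synthase subunit ATPD by 1.09 ± 0.47. LHCB1.3 stood at -0.70 (standard error 0.83; 1.22 in the second version) and RBCS1A, with 9 of 12 readings saturated in diseased silicon plants, at -0.19 ± 1.07 (1.83 in the first version). Neither passed the test. Batch medians were 1.18, 0.38 and 0.61 for photosystems and 1.24, 0.41 and 0.82 for carbon fixation.

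Among the genes lower with silicon in diseased leaves were the transcription factor gene WRKY65 at -1.31 ± 0.41 and the auxin-responsive IAA2 at -1.19 ± 0.21. P58IPK (AT5G03160, chromosome 5, 752634 to 752693), a co-chaperone of the endoplasmic reticulum, was called at -1.42 ± 0.37, but 5 of its readings in pathogen plants and 6 in diseased silicon plants were saturated, so the size of its change is not known. PR1 was called at -0.88 ± 0.11 (adjusted p = 0.0215), but 4 of its readings in diseased silicon plants were saturated, which can lower it there. With median centring PR1 stood at 0.22, where the median of all genes was 0.25. Of 22 salicylate genes 1 rose and 3 fell (median 0.021, adjusted p = 0.415; 2 and 3 adjusted over the list alone; -0.12 and adjusted p = 0.0285 in the second version). CBP60G was -0.47 ± 0.12, SARD1 -0.62 ± 0.48 but 0.12 in the second software version, and WRKY54 0.37 ± 0.28 but -0.11 in the second. PR2 (0.29 ± 0.55), PR5 (0.15 ± 0.96) and ICS1 (-0.12 ± 0.15) did not pass. Of 16 powdery mildew resistance genes 0 rose and 3 fell (median -0.013 with loess and 0.37 with median centring, adjusted p = 0.312). The vesicle protein VAMP722 was -1.13 ± 0.41 and its partner PEN1, which acts in resistance at the cell wall, -0.56 ± 0.22, but these read 0.22 and 0.13 in the second version, and SYP122 was -0.45 ± 0.17 but 0.23 with median centring. Of 21 immune receptor signalling genes 0 passed (median -0.041 with loess and 0.39 with median centring, adjusted p = 0.415).

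Camalexin, ethylene, oxidative stress and senescence lists had lower medians with loess, and with median centring none of the 4 passed (adjusted p = 0.615, 0.519, 0.537 and 0.519). Of 14 camalexin and indole genes 0 rose and 2 fell, with a median of -0.35 that was 0.17 with median centring (adjusted p = 0.00414, and adjusted p = 0.414 with an estimated correlation; 6 fell adjusted over the list alone). CYP71A13 was -0.57 ± 0.38 and AT3G54640 -0.38 ± 0.21, the latter 0.48 with median centring and 0.24 in the first software version, and PAD3 (-0.32 ± 0.20) did not pass. Of 22 ethylene genes 0 rose and 4 fell, with a median of -0.11 that was 0.28 with median centring (adjusted p = 0.00788, and adjusted p = 0.414 with an estimated correlation), including ERF2 (AT5G47220, chromosome 5, 19189763 to 19189704) at -0.96 ± 0.20 but 0.13 in the second version, and ACS2 at -0.61 ± 0.23. Of 18 oxidative stress genes 1 rose and 2 fell, with a median of -0.28 that was 0.16 with median centring (adjusted p = 0.0107, and adjusted p = 0.414 with an estimated correlation; 2 and 5 adjusted over the list alone). GSTF2 was -0.94 ± 0.19, GSTF7 -0.85 ± 0.18 but 0.22 with median centring, and the superoxide dismutase CSD2 0.84 ± 0.16. Of 10 senescence genes 0 rose and 2 fell, with a median of -0.38 that was 0.28 with median centring (adjusted p = 0.0107, and adjusted p = 0.432 with an estimated correlation). SAG13 fell by 0.68 (SD 0.20), with 0.14 on its other probe, and SAG21 was -0.72 ± 0.20 but 0.26 with median centring. Batch medians were -0.38, -0.24 and -0.34 for camalexin, -0.23, -0.017 and -0.19 for ethylene, -0.22, -0.12 and -0.30 for oxidative stress, and -0.46, -0.29 and -0.37 for senescence. In the day block camalexin, oxidative stress and senescence did not pass (adjusted p = 0.113, 0.131 and 0.131), nor did senescence with outlier spots kept (adjusted p = 0.064). None of the 4 passed in the first version (adjusted p = 0.119, 0.0537, 0.488 and 0.4 in the order of the medians), and in the second only camalexin did (adjusted p = 0.0285).

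Of 7 flavonoid genes 2 rose and 0 fell (median 0.20, adjusted p = 0.0107, and adjusted p = 0.414 with an estimated correlation; 5 rose adjusted over the list alone), CHS by 0.56 ± 0.19 and the flavonol synthase FLS1 by 0.51 ± 0.092. Of 4 root markers 2 fell and 0 rose (median -0.16, adjusted p = 0.0263, and adjusted p = 0.414 with an estimated correlation), RCI3 by 0.27 (SD 0.047) and COBL9 by 0.87 (SD 0.14), the latter 0.36 in the second version. Batch medians were 0.25, 0.21 and 0.23 for flavonoids and -0.11, -0.027 and -0.21 for root markers. Flavonoids did not pass in either version (adjusted p = 0.277 and 0.188) or with median centring (adjusted p = 0.491), and root markers in none of the 3 fits (adjusted p = 0.363, 0.236 and 0.131) or with outlier spots kept (adjusted p = 0.0687). Of 10 phosphate starvation genes 2 rose (median 0.14, adjusted p = 0.181), SPX1 by 0.54 ± 0.37 and SPX3 by 0.28 ± 0.15, the latter with 0 of 12 readings well above background in control plants. Of 4 guard cell and trichome markers 2 rose (median 0.18, adjusted p = 0.162), TGG1 by 1.26 ± 0.38. Of 11 protein folding genes 1 rose and 1 fell (median -0.20 with loess and 0.81 with median centring, adjusted p = 0.277; 1 and 2 adjusted over the list alone), the chaperone SHD by 0.48 ± 0.29 and BIP3 by -0.40 ± 0.046. Of 20 jasmonate genes 1 rose (median 0.011, adjusted p = 0.931), CORI3 by 0.71 ± 0.39, while VSP2 (-0.13 ± 0.14) and PDF1.2a (-0.59 ± 1.12) did not pass.

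The remaining lists held at most a single called gene in diseased plants. Flower markers had 1 lower gene of 6 (median -0.081, adjusted p = 0.162, and 0.032 with median centring; 2 adjusted over the list alone) and vascular markers 1 higher gene of 7 (median -0.095 with loess and 0.27 with median centring, adjusted p = 0.445; 1 and 1 adjusted over the list alone). With 0 called, abscisate genes stood at -0.019 with loess, 0.28 with median centring and 0.27 in the second version (adjusted p = 0.312, and 0.0406 in the second version), heat shock genes at -0.13, 0.27 and 0.30 (adjusted p = 0.162, and 0.0142 and 0.0397 in the versions, with -0.21 in the first), and sugar genes at -0.082 and 0.76 with loess and median centring (adjusted p = 0.415). Nitrogen, phenylpropanoid, clock and NIP aquaporin genes stood at 0.020, 0.083, 0.031 and 0.11 (adjusted p = 0.415, 0.599, 0.599 and 0.415), and reference genes at -0.018 with loess and 0.65 with median centring (adjusted p = 0.931).

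In all, 2554 of 20351 genes (12.5%) differed between diseased plants with and without silicon, 1601 higher and 953 lower, and 65 of them at least 2-fold (25 higher, 40 lower). None of the named genes stayed called in a fit without any 1 replicate: 0, 8 and 0 genes passed without replicate 1, 2 and 3. Higher genes made up 62.7% of the calls with loess, 91.2% of 6670 with median centring, 72.6% of 2362 with the authors' table, 46% of 1677 on the direct arrays and 47.9% of 5073 with day as a block. The first software version called 7024 genes, which held 2258 of the 2554, and the second 1967, which held 404; across genes the effects in the 2 versions correlated at -0.196, and 44.7% had the same sign in both. On the arrays that paired pathogen with diseased silicon plants, the ratios of a dye swap correlated at -0.0589, -0.367 and 0.14. Here too the part that turned with dye and version varied more between genes than the common part.

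The difference of the pathogen effects passed for SAG13 alone, at -1.36 ± 0.30 (adjusted p = 0.0303, -0.44 on its other probe). With silicon SAG13 was higher in healthy (uncalled) and lower in diseased plants, like PR1. Others did not pass at an adjusted p of 0.0731: PR1, with 4 saturated readings in diseased silicon plants, at -1.69 ± 0.50, GSTF7 at -1.37 ± 0.39, ERF2 at -0.89 ± 0.23, NPQ4 at 1.39 ± 0.60, HCEF1 at 0.93 ± 0.21 and CHS at 0.91 ± 0.26. PR2 was -0.48 ± 0.30, PR5 -0.43 ± 0.57, ICS1 -0.14 ± 0.22, PAD3 -0.35 ± 0.52, PDF1.2a -1.40 ± 1.39, VSP2 -0.11 ± 0.47, LHCB1.3 -0.67 (standard error 1.17) and RBCS1A, with 19 saturated readings, 0.030 ± 1.24. By limma 4831 genes had an unadjusted p below 0.05 and 811 an adjusted p below 0.1. SAG13 was not called without any 1 replicate, with median centring, with outlier spots kept or with the mean of all probes (0 calls in each), nor among the 4 genes called with no replicate block. It was among 271 calls with the Agilent processed intensities and 376 with the deposited log2 values. It was not among the 1 and 32 calls of the software versions, the 142 with scaling between arrays, or the 1964 with day as a block, of which 573 were higher.

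As lists, photosynthesis genes stood higher in this difference. The median was 0.77 for 30 photosystem genes (adjusted p = 1.98e-05, and adjusted p = 0.419 with an estimated correlation), of which 13 rose and 1 fell adjusted over the list alone, and 0.72 for 18 carbon fixation genes (adjusted p = 4.32e-05, and adjusted p = 0.351 with an estimated correlation), of which 6 rose over the list alone. Flavonoid genes stood at 0.33 (adjusted p = 0.00177; 3 of 7 rose over the list alone), root markers at -0.24 (adjusted p = 0.0177; 2 of 4 fell), and camalexin genes at -0.43 with loess and 0.016 with median centring (adjusted p = 4.13e-05; 4 of 14 fell). These 3 had an adjusted p = 0.34 with an estimated correlation. Oxidative stress genes stood at -0.26 (adjusted p = 0.00176; 4 of 18 fell), and with loess and median centring senescence genes at -0.57 and 0.056 (adjusted p = 0.00177; 2 of 10 fell) and ethylene genes at -0.14 and 0.17 (adjusted p = 0.00177; 1 rose and 5 fell of 22). These 3 had an adjusted p = 0.351 with an estimated correlation. Protein folding genes stood at -0.26 and 0.56 (adjusted p = 0.0256, and adjusted p = 0.419 with an estimated correlation; 1 of 11 fell). Batch medians were 0.56, 0.69 and 0.22 for photosystems, 0.997, 0.57 and 0.56 for carbon fixation, and 0.42, 0.24 and 0.42 for flavonoids. In the same order they were -0.43, -0.39 and -0.46 for camalexin, -0.94, -0.066 and -0.62 for senescence, -0.45, -0.22 and -0.43 for oxidative stress, -0.22, -0.28 and -0.35 for root markers, -0.18, -0.12 and -0.31 for ethylene, and -0.0012, -0.36 and -0.40 for protein folding. In the day block senescence, oxidative stress, root markers and protein folding did not pass (adjusted p = 0.0883 for each). In the first version oxidative stress, root markers and protein folding did not pass (adjusted p = 0.249, 0.181 and 0.577), nor did flavonoids, senescence and root markers in the second (adjusted p = 0.111, 0.304 and 0.206). With median centring flavonoids, camalexin, oxidative stress, senescence, ethylene and protein folding did not pass (adjusted p = 0.0837, 0.0994, 0.0687, 0.0994, 0.0994 and 0.981).

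Salicylate genes stood at -0.068 in this difference with loess and 0.27 with median centring (adjusted p = 0.0764; 2 of 22 fell adjusted over the list alone; adjusted p = 0.0224 with outlier spots kept, and -0.19 with adjusted p = 2.39e-05 in the second version), and powdery mildew resistance genes at -0.060 and 0.28 (adjusted p = 0.193; 1 rose and 3 fell of 16). NIP aquaporins stood at 0.18 (adjusted p = 0.102, and 0.032 in the day block; 3 of 5 rose over the list alone), sugar genes at -0.22 with loess and 0.35 with median centring (adjusted p = 0.205; 1 of 6 fell), and guard cell and trichome markers at 0.14 (adjusted p = 0.205; 1 of 4 rose). With 0 called either way, jasmonate genes stood at -0.045 and 0.40, immune receptor signalling genes at -0.064 and 0.37, and abscisate genes at -0.037 and 0.20 with loess and median centring (adjusted p = 0.382, 0.146 and 0.193). Nitrogen genes were at -0.097 and 0.33, heat shock genes at -0.12 and 0.19, and vascular markers at -0.015 and 0.15 (adjusted p = 0.249, 0.193 and 0.673). Phenylpropanoid, clock, phosphate, flower and reference lists had medians of 0.0078, 0.11, 0.10, -0.0024 and 0.015 (adjusted p = 0.52, 0.193, 0.432, 0.339 and 0.784).

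**Figure D4:**
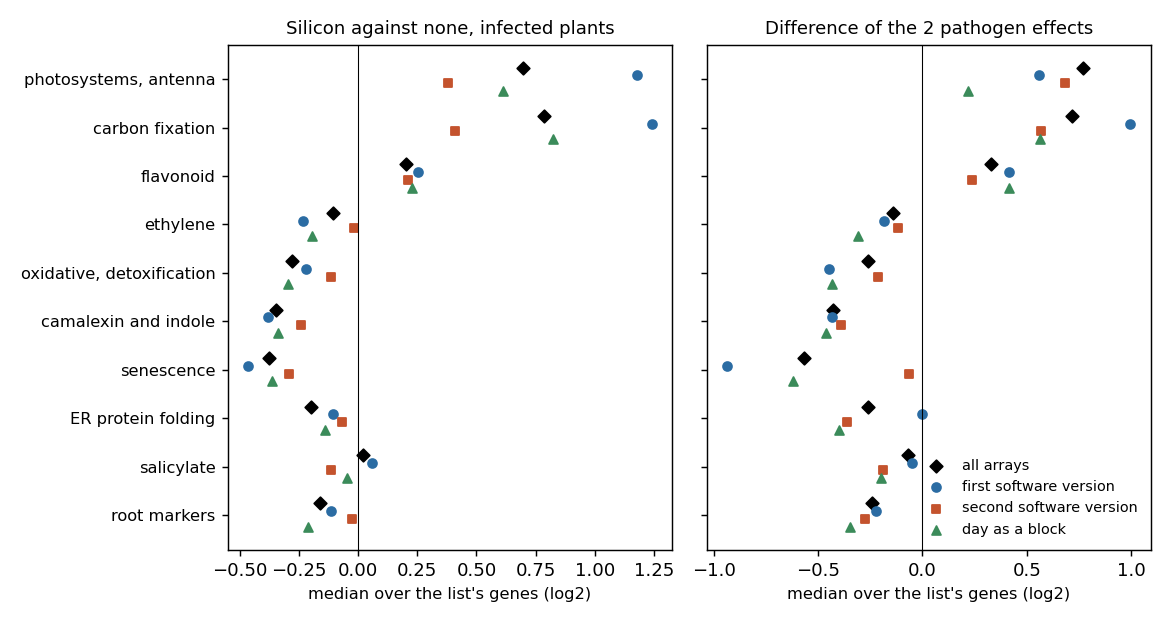
Median log2 values (horizontal axis) of 10 gene lists for silicon against none in diseased plants (left) and for the difference of the pathogen effects (right), with all arrays, either software version and day as a block shown by separate markers. Photosystem genes stood at 0.70 and 0.77 with all arrays, and at 0.61 and 0.22 with day as a block; with median centring the camalexin medians were 0.17 and 0.016 in place of -0.35 and -0.43.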

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

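Tests within the software versions and with day as a block were chosen only after the results were seen. So were counts of splits keeping the diseased groups.

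SAG13, a gene of ageing leaves, stood out because its rise with the fungus differed with silicon (-1.36), partly from healthy plants. For the same reason, a difference between groups, 9 gene lists stood out by their median difference of the pathogen effects: photosystems (0.77), carbon fixation (0.72), flavonoid (0.33), senescence (-0.57), camalexin and indole (-0.43), oxidative stress (-0.26), protein folding (-0.26), root markers (-0.24) and ethylene (-0.14). Probes that name no gene stood out because no result had been reported on them: of 3064 measured probes for chromosome regions 640 changed with the fungus without silicon and 657 with silicon, and of 1149 probes for other sequences 345 and 341. These were 20.9%, 21.4%, 30% and 29.7% of the probes, against 53% and 55.3% of the genes.

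The number of called genes was compared with regroupings of the same plants. Each pair of groups allows 10 splits, of which 1, the real split, had at least as many calls, and 10 splits are too few for a share under 0.05. The real counts were 10785, 11251, 1 and 2554 for the pathogen effect without and with silicon and the silicon effect in healthy and diseased plants, and the highest other counts were 1, 0, 0 and 3. For the difference of the pathogen effects, 10 of 100 splits drawn had at least the real count of 1, so chance was not excluded for that count, and the highest other count was 2299. That split left the diseased plants in their real groups, which part by 2554 calls, and mixed the healthy plants without parting each loop. Of the drawn splits 12 left the diseased plants so, and apart from the real one and this one they called at most 1 gene, so the cause stays open. Of the drawn splits 19, the real one included, parted every loop as the real one does; they are too few for a share under 0.05, and the highest other count among them was 0.

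Photosystem and carbon fixation genes fell less with the fungus in silicon plants, by a median of 0.73 over 48 genes (SD 0.42 over 3 loops). The value did not rest on a single software version (0.69 and 0.67). A gene's dye bias drops out within either by design and was not tested. The value lay at percentile 100 of 10000 random lists matched for intensity (upper bound 0.016). Photosynthesis genes vary together (correlation 0.474 and 0.375) and random ones need not, so brightness was not excluded. A smaller response of all falling genes may be part of it: among lists matched also for the pathogen effect the value lay at percentile 99.9, but its excess over the upper bound of their values, 0.57, was less than the SD over loops, and the matched genes had fallen less by 0.34 on average. A slower loss of photosynthetic transcripts in silicon plants stays open, and the day-block values of 0.22 and 0.56 for the lists are part of that doubt.

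Genes that rose with the fungus were slightly higher in healthy silicon plants, with a median of 0.063 for genes that had risen by 1 to 2, 0.15 for 2 to 3, 0.32 for 3 to 4 and 0.64 above 4, where a loop held as few as 3 genes. A loop's silicon effect correlated with the other loops' pathogen effect at 0.3, 0.154 and 0.0744. These share no plants, so shared control plants cannot produce this, but genes are not independent replicates. A small share of RNA from diseased leaves, 3.11%, could produce the values of risen genes. Those risen by 2 to 3 missed their prediction of 0.17 by -0.014 (SD 0.077). Genes fallen by over 2 or by 1 to 2 stood at -0.18 and -0.096, lower than the predictions of -0.036 and -0.027. The gaps of -0.14 and -0.069 lay within the SD over loops of 0.20 and 0.16 and decided nothing. Neither an own effect of silicon nor a dye bias unequal between versions was tested apart from such RNA.

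Among the probes that name no gene, 131 were called between diseased plants with and without silicon, and 121 of these (92.4%) were lower with silicon. Among 10443 genes matched for brightness to all such probes, called or not, 31.5% of calls were lower (37.3% for all genes). Brightness thus stays open. The called probes had a median of -0.79 in the first software version and -0.095 in the second, so they were lower in both but mainly in the first, and a technical part could not be excluded.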

How the results depend on the processing

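Fits within a software version, with correlated dye-swap arrays, day as a block or outlier spots kept were chosen only after the results were seen. Of the values of named genes over all alternatives, 3857 stayed the same, 354 were weaker, 67 stronger and 31 reversed; of the values of lists 939 stayed the same, 136 were weaker, 36 stronger and 9 reversed. Fits without a replicate rest on 2 loops and assume that the spread of those is the spread of all. Signal over background limits the dim genes: 10559 genes were well above background in every reading.

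Pathogen effects kept their counts within 1.5 times except where fewer genes were tested or a fold was required: 6464 and 6683 genes without and with silicon in every reading, and 1905 and 1428 with at least 2-fold. Leaving out a replicate gave 7612 to 9201 and 7876 to 9095. With no replicate block, which drops the pairing of same-numbered plants, 9909, 9774 and 2858 genes were called for the pathogen effects and the silicon effect in diseased plants; it also ended the call of ARR15 (0 in healthy plants) and of SAG13 (4 other genes called), and it moved no other count by over 1.5 times.

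Silicon in healthy plants gave 0 calls without background subtraction, without any replicate, and with median centring, Agilent intensities or every reading. It gave 0 with no replicate block, direct arrays, a 2-fold change and the first version. It had 12 with scaling between arrays, 2 with the authors' table, 56 with 24 arrays as independent, 29 with 12 dye-averaged ratios, 95 with correlated dye-swap arrays, 27 with day as a block and 1564 in the second version. Silicon in diseased plants gave 6670 calls with median centring, 1630 with scaling, 1627 in every reading. It gave 5956 with 24 arrays and 5330 with 12 ratios as independent, 1677 on direct arrays, 6460 with correlated arrays, 5073 with day as a block, 7024 in the first version, 65 with 2-fold, and 0 to 8 without a replicate. For the interaction these were 0 with median centring, outlier spots kept, the mean of all probes and without a replicate. They were 142 with scaling, 271 with Agilent intensities, 376 with the authors' table and 32 in the second version. They were 5798 and 5369 with arrays or ratios as independent, 6385 with correlated arrays and 1964 with day as a block. Fits of 24 arrays count more units than the 12 plants, also with correlated arrays or day (dye-swap correlation -0.0637 and -0.00275). The 12 ratios share plants. Fits within a version carry a gene's dye bias in full, except in the interaction. For others the cause was not tested.

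Response ratios with median centring were 1.75 for risen and 0.565 for fallen genes; the cause was not tested. Without a replicate they were 0.897 to 0.970 and 0.778 to 0.886. With an estimated correlation 0 lists passed in any of the 5 contrasts, against 12, 11, 8, 8 and 9. Lists passing with silicon in the pathogen effect were 5 in the first version. In healthy plants they were 2 to 9 without a replicate (2 without replicate 1 and 2 without replicate 3), 4 with day as a block, 3 in the first and 5 in the second version. In diseased plants they were 4 with median centring, 4 with day as a block and 3 in the first version, and for the interaction 3 with median centring; the cause was not tested.

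Lists whose test turned direction were heat shock with silicon in the second version (0.27), and in healthy plants protein folding (-0.12) and carbon fixation (0.36) in the first version. The test compares means, and the main medians of heat shock with silicon (0.032) and of carbon fixation (0.018) had the same sign as these. In healthy plants photosystems (-0.36), senescence (-0.14) and heat shock (0.21) turned in the second version, and phenylpropanoids without replicate 3 (-0.013, against 0.16 without replicate 2). In diseased plants abscisate (0.27) and heat shock (0.30) turned in the second version. With median centring the medians, though not the tests, of called lists also turned: abscisate with silicon (0.030), and in diseased plants camalexin (0.17), ethylene (0.28), oxidative stress (0.16) and senescence (0.28). In the interaction these were camalexin (0.016), ethylene (0.17), senescence (0.056) and protein folding (0.56). The median of all genes moved as well with median centring, to 0.36 for the pathogen effect with silicon, 0.25 for silicon in diseased plants and 0.26 for the interaction. Of these lists only ethylene and senescence in diseased plants and protein folding exceeded that common shift.

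Genes that reversed were for the pathogen effect without silicon SEP3 in the second version (0.63) and EF1A with median centring (-0.57), 24 independent arrays (-0.13) and correlated arrays (-0.12). With silicon they were GLU1 (0.22), HSP23.6 (0.40), LUX (0.092) and NIP6;1 (0.26) with median centring, NIP6;1 with day as a block (0.090) and in the first version (0.11). In the second version they were COBL9 (0.77), SEP3 (0.35), EF1A (-0.19), HSP23.6 (0.53), GRP7 (0.44), ELF3 (-0.042) and NIP1;2 (-0.064). For silicon in diseased plants they were SYP122 (0.23), AT3G54640 (0.48), GSTF7 (0.22), SAG21 (0.26) and PR1 (0.22) with median centring, AT3G54640 (0.24) and RBCS1A (1.83) in the first version. GLU1, LUX, NIP6;1, SYP122, GSTF7 and PR1 did not exceed the common shift with median centring. In the second version the others were VAMP722 (0.22), PEN1 (0.13), SARD1 (0.12), WRKY54 (-0.11), ERF2 (0.13), COBL9 (0.36) and LHCB1.3 (1.22). As for the lists, reversals within a version cannot be told from dye bias. For the other reversals the cause was not tested.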

Other observations

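The gene families in this part were chosen only after the main results were seen, by words in the annotation, and were tested like the lists. Plastid ribosomal proteins fell with the fungus in plants without silicon for 19 of 19 genes (median -1.60, adjusted p = 1.91e-08, and adjusted p = 0.355 with an estimated correlation). Batch medians were -1.21, -1.88 and -1.47. With silicon 15 fell, with a median of -0.85 that was 0.14 with median centring (adjusted p = 1.24e-05, and adjusted p = 0.549 with an estimated correlation). Batch medians were -0.58, -1.15 and -1.15. In diseased plants 9 were higher with silicon (median 0.61, adjusted p = 7.37e-06, and adjusted p = 0.704 with an estimated correlation), with 0.66, 0.49 and 0.48, and in healthy plants 0 changed (median -0.095, adjusted p = 0.00843, and adjusted p = 0.834 with an estimated correlation). The batch medians there were 0.058, -0.27 and 0.12, and the family did not pass in the first version or the day block (adjusted p = 0.685 and 0.552). Auxin-responsive proteins fell without silicon for 58 of 108 genes and rose for 22 (median -0.22, adjusted p = 0.000234, and adjusted p = 0.317 with an estimated correlation). Their batch medians were -0.23, -0.24 and -0.18.

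WRKY transcription factors rose with the fungus in plants without silicon for 40 of 62 genes and fell for 5 (median 0.53, adjusted p = 1.03e-07, and adjusted p = 0.317 with an estimated correlation). With silicon 35 rose and 5 fell (median 0.37, adjusted p = 2.17e-05, and adjusted p = 0.482 with an estimated correlation). The WRKY batch medians with silicon were 0.40, 0.40 and 0.30. In diseased plants 1 was higher and 6 were lower with silicon, with a median of -0.086 that was 0.21 with median centring, and batch medians of -0.093, -0.051 and -0.13 (adjusted p = 0.00209, and adjusted p = 0.704 with an estimated correlation). They did not pass in the first version or the day block (adjusted p = 0.0759 and 0.0573). Batch medians without silicon were 0.45, 0.50 and 0.51.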
